A study of Mus musculus with 10 samples.

How the data were processed

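Single-cell RNA was measured in mouse tibialis anterior muscle with the 10x Genomics 3′ kit, version 3, in 10 libraries with 1 library per group. Per the labels, 6 libraries came from uninjured muscle and from muscle 2 and 10 days after injury, each from mice with Gsdmd deleted by Lyz2-Cre (Gsdmd cKO) and from floxed controls. The other 4 came from wild-type mice injured with cardiotoxin and given a control treatment or EET, as the labels abbreviate it, at 3 and 10 days. The labels do not give the number of animals per library, nor the floxed exons of Gsdmd. Muscle was digested with collagenase and dispase and then with trypsin, and red blood cells were lysed.

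The deposited files held raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, with 55357 features and 112436 barcodes. Reads were demultiplexed with bcl2fastq 2.20 and counted with Cell Ranger on the GRCm38 mouse build, according to the submitters' processing notes, which also name Seurat 4.0.1. The notes give Cell Ranger 3.1.0, while the matrix headers name 7.0.0 in the Gsdmd libraries and 7.1.0 in the libraries with EET or control treatment. Of the feature identifiers, 52081 were found in the GENCODE M21 annotation, so no genome positions are printed. Whether intronic reads were counted is not stated.

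Barcodes with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs were kept. Doublets were scored in each library against simulated doublets. The cells with the highest scores were removed, up to an expected share of 0.8% per 1000 barcodes, which took between 4.20% and 11.9% of the filtered barcodes. After this step 88127 cells remained. They were clustered together without batch correction after log normalisation, on 2000 variable genes, 30 principal components, a graph of 20 nearest neighbours and Leiden clustering at resolution 1. This gave 39 clusters, named by marker lists for 15 cell classes, and 5 clusters stayed unnamed. In 4 of these under 3 markers of the best-scoring class were raised. Among them was cluster 21, with 1642 cells, whose leading genes Pecam1, Egfl7 and Cdh5 are endothelial markers, while its best-scoring class was erythroid/platelet. In cluster 25, with 973 cells, 30 endothelial markers were raised, but its 10 leading genes held no endothelial and 1 tenocyte marker, Clu, so the rule left it out of the endothelial-like class. Class names end in "-like" because they rest on transcripts alone.

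UMIs were summed per library and class and scaled to CPM, the count per 1000000 UMIs of the class total. A log2 ratio was taken after adding 10 CPM to both values. The Gsdmd ratio was taken without that addition. A gene was measured when the higher library had at least 50 CPM and 20 counts, and a class was compared when both libraries held at least 50 such cells. Genes at least 2-fold apart were counted. With 1 library per group there is no replicate error, so no test, p-value or standard error was computed, and cells were not used as replicates. Intervals are exact Poisson intervals for CPM and exact Clopper-Pearson intervals for shares of cells, at 95%, and those of list medians come from 1000 Poisson draws. These intervals cover counting error only. With free RNA taken off, intervals of list medians come instead from resampling the list's members 1000 times, as if they were independent of each other. A further pair, the floxed control against the control treatment at 10 days, was compared in the same way as a yardstick of how far control libraries of different experiments lie apart.

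The comparisons, the marker lists, 27 gene lists and the rule for named genes were fixed before the data were examined. Lists reported here cover inflammatory cytokines and chemokines, dissociation stress and immediate early genes, interferon response, monocyte genes, resident macrophage genes, repair-associated macrophage genes, MHC class II presentation, pyroptosis, arachidonate and epoxyeicosanoid enzymes, efferocytosis, PPAR and LXR targets, complement, glycolysis, oxidative phosphorylation, cholesterol synthesis, cell cycle, stem cell quiescence, myogenic commitment, extracellular matrix, senescence, growth factors, angiogenesis and fast-fibre transcripts. The last list served as a check for free RNA. A list median needed at least 5 measured members. It was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Of 378 list medians in the 5 main comparisons, 195 lay outside the 2.5 to 97.5 percentiles of the random lists. In older lists 6 symbols were matched by identifier, and 4 listed symbols had no feature.

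Genes were named by rule. In each comparison these were the 10 with the largest log2 ratio each way in monocyte/macrophage-like cells and the 4 each way in fibro-adipogenic progenitor (FAP)/fibroblast-like, muscle stem cell (MuSC)/myoblast-like, endothelial-like and neutrophil-like cells. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and unnamed gene models were left out, as were genes with under 1/5 of the CPM of another class in the same library. The 2 members with the largest ratio of each list, Gsdmd and markers used for a check were also eligible. Other genes are marked where they appear. Some genes that met this rule are not reported here.

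The counting procedure was tested on simulated data, in which 200 genes were shifted in each main comparison. Both simulated libraries were Poisson draws from the control library's sum, so they differ by counting error and the shifts only. The simulation therefore cannot show how many calls in the real libraries come from differences between libraries. At 2 days it recovered every shifted gene in monocyte/macrophage-like cells. In the smaller uninjured pair it recovered 84 of 94 genes shifted by a log2 ratio of 1.5 and 98 of 106 shifted by 2, with 4 false calls.

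Alternatives tried were a pseudocount of 1 CPM, TMM scaling, minimum levels of 20 and 100 CPM, the mean of per-cell CPM, keeping doublets, a stricter cell filter of 1000 UMIs, 500 genes and 10% mitochondrial UMIs, clustering at resolution 0.5 and 2, thinning cells to 1000 UMIs, and shares without neutrophil-like or erythroid cells. Cells with under 1000 UMIs were left out of the thinned sums. Male or female cells alone at 10 days, the largest shared cluster alone, list medians in cluster 13, list medians after thinning, shares with unnamed clusters 10 and 31, male cells of the floxed control in the yardstick pair and the removal of free RNA were chosen after seeing the data. For the last, the profiles of monocyte/macrophage-like and neutrophil-like cells were subtracted from the other classes in the shares that their Lyz2 and S100a9 levels gave, between 5.35% and 7.16% for the former. List members of which free RNA was at most 50% in both libraries were also taken alone. The code used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors only.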

Results

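Transcripts of single cells from mouse tibialis anterior muscle were counted in 10 libraries, 1 per group, so no value has a replicate library. Both Gsdmd libraries at 10 days held male and female cells, thus of more than 1 animal. Male and female cells are set side by side below, but they share the handling of their library. The Gsdmd cKO libraries held 51252873 UMIs in uninjured muscle, 97856973 at 2 days and 67664495 at 10 days after injury. The floxed control libraries held 20278140, 82648170 and 74584945 at the same times. At 3 days, the control treatment and EET libraries held 102413014 and 102198345, and at 10 days 77173330 and 91489382. The libraries had between 6494 and 15164 barcodes, against the 8,000 to 10,000 cells that the labels name as the aim. Cells kept per library ran from 3219 in the uninjured floxed control to 11742 in the EET library at 3 days. More than 20% mitochondrial UMIs were found in 59.7% of the barcodes of the uninjured Gsdmd cKO library and in 48.0% of those of the uninjured floxed control. That share was between 0.232% and 17.2% in the 8 injured libraries. At 10 days it was 17.2% in the Gsdmd cKO and 4.43% in the floxed control library, and 0.523% with EET and 3.94% with control treatment. Shares of kept cells in these pairs were thus taken after unequal losses.

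Gsdmd, the gene for the pore-forming protein of pyroptosis, was lower in monocyte/macrophage-like cells of every Gsdmd cKO library. At 2 days it was at 19.0 CPM (17.9–20.2) in the Gsdmd cKO library and 37.6 CPM (35.9–39.3) in the floxed control, a log2 ratio of −0.98 (−1.09 to −0.87). At 10 days the values were 17.0 CPM (13.7–20.9) and 31.4 CPM (27.7–35.5), a log2 ratio of −0.89 (−1.25 to −0.54). In uninjured muscle only 12 and 13 counts stood behind 12.6 and 28.6 CPM, and the interval of the log2 ratio of −1.19 reached from −2.45 to 0.06. Neutrophil-like cells at 2 days had 30.2 CPM (24.0–37.5) in the Gsdmd cKO library and 49.3 CPM (41.8–57.9) in the floxed control. In endothelial-like cells, in which Lyz2-Cre is not known to act, Gsdmd stood at 18.6 and 18.2 CPM at 2 days and at 27.9 and 31.7 CPM at 10 days. It stood in FAP/fibroblast-like cells at 10.0 and 12.8 CPM at 2 days and at 16.8 and 15.1 CPM at 10 days. Tenocyte-like cells at 10 days had 5.05 CPM (2.89–8.21) in the Gsdmd cKO library and 12.7 CPM (8.32–18.7) in the floxed control, from 16 and 26 counts. In endothelial-like, FAP/fibroblast-like and MuSC/myoblast-like cells, the last at 9.95 and 10.9 CPM, the intervals at 10 days overlapped. With few counts in 1 class of several, it was left open whether a lower level is limited to classes with known Lyz2-Cre activity. The EET and control treatment libraries had 48.9 and 47.3 CPM in monocyte/macrophage-like cells at 3 days and 46.9 and 39.8 CPM at 10 days. At 2 days a Gsdmd UMI was seen in 13.4% of monocyte/macrophage-like cells of the Gsdmd cKO library, with a median of 7018.5 UMIs per cell, and in 29.2% of those of the floxed control, with 8841.5. In FAP/fibroblast-like cells, which had 27473 and 32741 UMIs per cell, the shares were 23.6% and 31.9%. The labels do not say which exons are floxed, and the kit reads the 3′ end of transcripts, so tags outside the deleted part would still be counted and this check is partial.

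Lyz2, the lysozyme gene whose locus carries Cre, was also lower in monocyte/macrophage-like cells of the Gsdmd cKO libraries. Its level was 5319 against 10997 CPM in uninjured muscle, 7544 against 14872 CPM at 2 days and 8362 against 18933 CPM at 10 days. Its close paralog Lyz1 was higher at each time, with 888 against 218 CPM, 212 against 23.6 CPM and 880 against 78.6 CPM. The paralogs are near-identical in sequence, so the split of tags between them is uncertain.

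**Figure D1:**
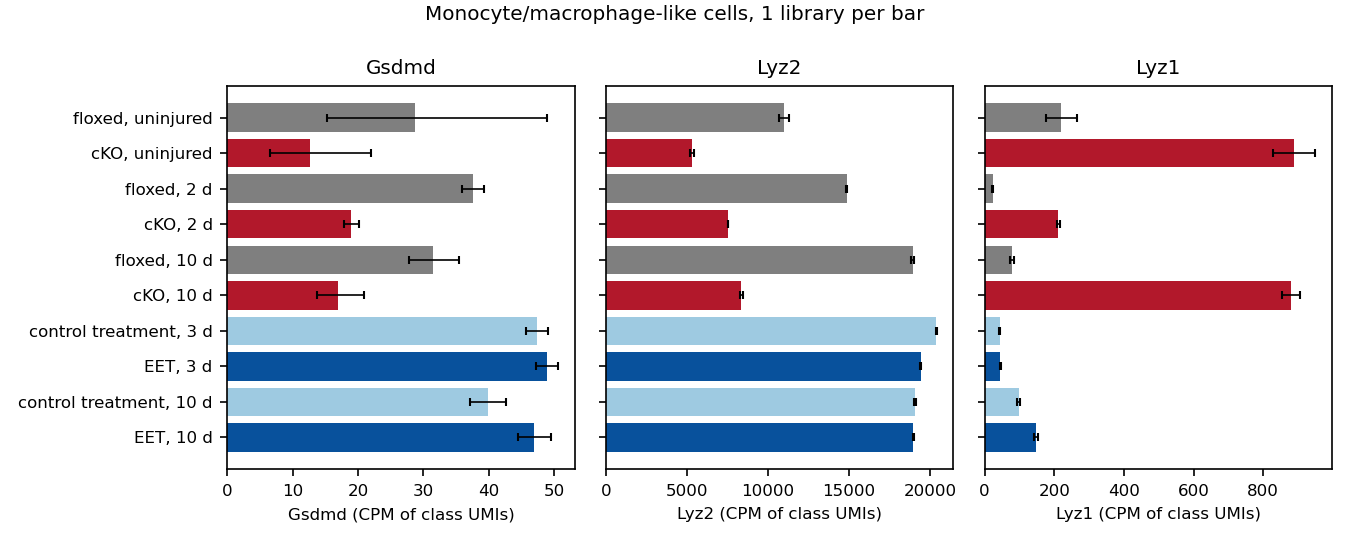
Bars give Gsdmd, Lyz2 and Lyz1 in CPM of class UMIs in monocyte/macrophage-like cells of each of the 10 libraries, with exact 95% Poisson intervals. Gsdmd is lower in each Gsdmd cKO library than in the floxed control of the same time, at 19.0 against 37.6 CPM at 2 days.

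Shares of the cell classes differed with time after injury. Monocyte/macrophage-like cells made up 2.58% of kept cells in the uninjured floxed control, 58.3% at 2 days and 11.5% at 10 days. They made up 71.2% in the control treatment library at 3 days and 27.1% at 10 days. Neutrophil-like cells were 18.2% of the floxed control library at 2 days. Endothelial-like cells were 53.2% of the uninjured floxed control and 34.01% of the uninjured Gsdmd cKO library.

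**Figure D2:**
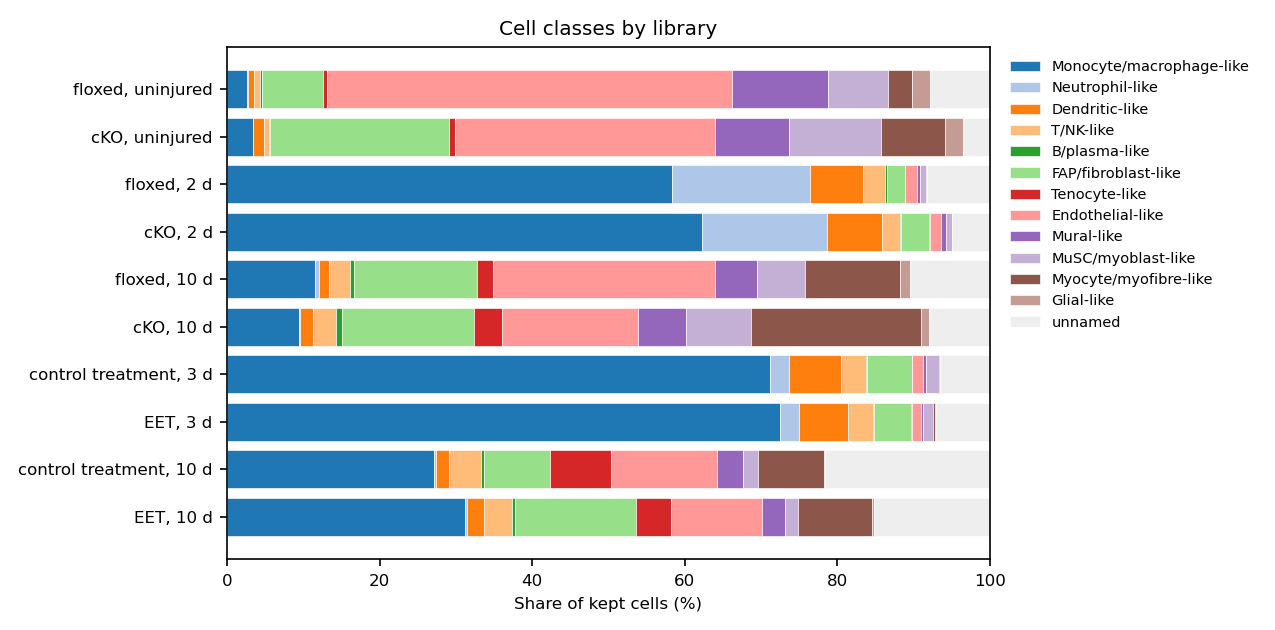
Stacked bars give the share of kept cells in each class, in percent, for each of the 10 libraries. The monocyte/macrophage-like share is largest at 2 and 3 days after injury, between 58.3% and 72.6%.

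The comparison of Gsdmd cKO with floxed control muscle asks how the cells of injured muscle differ when Gsdmd is deleted in Lyz2-expressing cells. At 2 days, inflammatory cytokine and chemokine genes were higher in monocyte/macrophage-like cells of the Gsdmd cKO library. Of 17 measured genes of the list 12 were higher, 9 of them at least 2-fold, and the median log2 ratio was 1.17 (1.15–1.20). Il1b, the gene for the cytokine interleukin-1β, was at 1143 against 319 CPM, and Cxcl2, a neutrophil-attracting chemokine, was at 4531 CPM (4513–4549) against 1387 CPM (1377–1398). Tnf, the gene for tumour necrosis factor, was at 400.1 against 119.9 CPM, and Cxcl1 at 329 against 107 CPM. Among the genes with the largest ratios were also Lyz1, Cd83, a surface marker of activated antigen-presenting cells, at 180.2 against 30.6 CPM, Tnfsf9, Dusp2, Nfkbiz, Ifrd1 and Tnfaip3, an inhibitor of NF-κB signalling, at 315 against 101 CPM. All 17 measured dissociation stress and immediate early genes were higher as well, with a median of 0.83 (0.81–0.84), led by Nr4a1 at 429 against 152 CPM and Egr1 at 1051 against 422 CPM.

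Interferon-response genes were lower in the same cells of the Gsdmd cKO library at 2 days, 21 of 22, with a median of −0.52 (−0.54 to −0.49). Mx1, an antiviral GTPase gene, was at 38.1 against 78.0 CPM, Ifit1 at 55.8 against 108 CPM and Rsad2 at 152 against 272 CPM. The largest ratios on the lower side also included Pgap6, at 28.5 against 89.9 CPM, Lyz2, Ifit3, Ifit2, Ifi209, Stat2 and the chemokine gene Ccl8, at 139 against 230.3 CPM. All 14 measured monocyte genes were lower, with a median of −0.24, and the medians of resident and repair-associated macrophage genes were −0.15 and −0.13. MHC class II genes had a median of 0.25. The medians of the pyroptosis list, −0.02 over 7 genes, and of the arachidonate and epoxyeicosanoid enzymes, 0.00 over 8 genes, lay within those of random lists. The mean of the pyroptosis list was 0.36, above its median. Within that list, Il1b and the inflammasome sensor gene Nlrp3, at 106 against 41.4 CPM, had the largest ratios.

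The same inflammatory list was higher at 2 days in classes in which Lyz2-Cre is not known to act. Its median was 1.21 in FAP/fibroblast-like cells, with 12 of 12 genes higher, 1.08 in endothelial-like cells, with 11 of 15, and 1.03 (0.83–1.20) in MuSC/myoblast-like cells, with 7 of 9. With free RNA of macrophage-like and neutrophil-like cells taken off, these medians were 0.99, with 12 of 12 genes higher, 1.11, with 13 of 15, and 0.61, with 6 of 9. In neutrophil-like cells it was 0.81, with 17 of 20 genes higher. Stress and immediate early genes had medians of 0.87, 0.84, 0.53 and 0.52 in these classes, in the same order, and with free RNA taken off those of the first 3 were 0.84, 0.87 and 0.30. With cells thinned to 1000 UMIs the stress median of MuSC/myoblast-like cells was −0.0053, over 6 measured genes. FAP/fibroblast-like cells of the Gsdmd cKO library had 58.4 against 14.8 CPM of the immediate early gene Egr2 and 124 against 41.3 CPM of the chemokine gene Cxcl10, with Ier3 and Nr4a2 next, and had less Apod, Pttg1, Tmem254a and Plac9a. Cholesterol synthesis genes were higher in these cells, 11 of 11, with a median of 0.31. Endothelial-like cells had 112.4 against 18.2 CPM of the chemokine gene Cxcl9 and 1155 against 436 CPM of Fos, with Cenpf and Hivep2 next. They had 27.4 against 88.8 CPM of Esm1, a gene of sprouting endothelium, and less Rsad2, Isg15 and Tmem254a. Neutrophil-like cells had 344 against 54.9 CPM of Il23a, which encodes a subunit of interleukin-23, and 91.6 against 11.4 CPM of Il1a, with Dusp2 and Icam1 next. Their 21 measured interferon-response genes were all lower, with a median of −0.65, and Oasl1, Eif2ak2, Ctse and Id1 were the genes furthest lower. Hmga1 was higher in MuSC/myoblast-like cells and its near-identical copy Hmga1b lower, so their values are uncertain. Klf4, Mid1 and Dleu2 were also higher there, and Pttg1, Tmem254a and Nol9 lower.

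At 2 days 37 genes were at least 2-fold higher and 1 lower of 3103 measured in monocyte/macrophage-like cells, 23 and 0 in FAP/fibroblast-like cells, 28 and 4 in endothelial-like cells and 11 and 4 of 3252 in MuSC/myoblast-like cells. The single gene lower in monocyte/macrophage-like cells was Pgap6. The 4 lower in MuSC/myoblast-like cells were Hmga1b, Pttg1, Tmem254a and Plac9a, and the 4 in endothelial-like cells were Esm1, Rsad2, Lyz2 and Gal. Plac9a in the former and Lyz2 and Gal in the latter class were named after their values were seen. The counts in neutrophil-like cells were 39 higher and 10 lower, or 48 and 5 under TMM scaling. Monocyte/macrophage-like cells made up 62.2% (61.3–63.1) of the Gsdmd cKO library and 58.3% (57.2–59.3) of the floxed control, a difference of 3.96 points (2.59–5.33). Unnamed cells were 4.90% and 8.23% of these libraries, and with unnamed cluster 10 counted in the class the difference was 0.696 points (−0.632 to 2.03), or 0.660 with clusters 10 and 31. The MuSC/myoblast-like shares were 0.685% and 0.765%, a difference of −0.0802 points (−0.330 to 0.161). The control pair used as a yardstick had 98 genes higher and 22 lower in monocyte/macrophage-like cells.

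**Figure D3:**
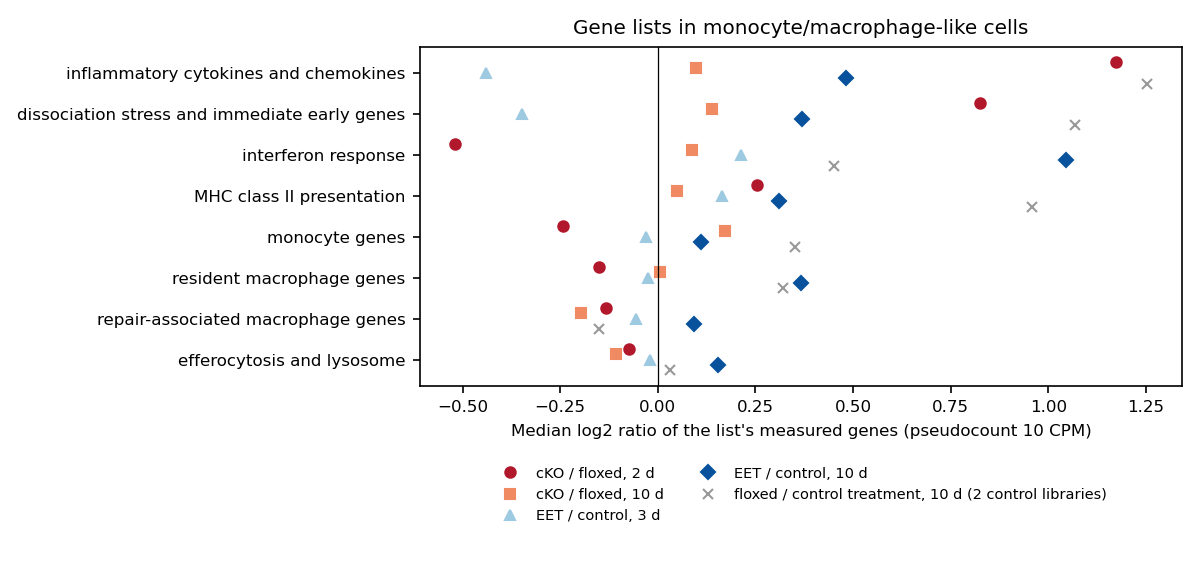
Points give the median log2 ratio of 8 gene lists in monocyte/macrophage-like cells for 4 comparisons and for the pair of control libraries at 10 days. The inflammatory list lies at 1.17 for Gsdmd cKO at 2 days and at 1.25 between the control libraries.

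At 10 days the Gsdmd cKO and floxed control libraries lay closer together in monocyte/macrophage-like cells. After Lyz1, the genes with the largest ratios on the higher side were Cxcl9, at 132.2 CPM (122.6–142.3) against 33.5 CPM (29.7–37.6), and the heat shock genes Hspa1b, at 161 against 69.4 CPM, and Hspa1a, at 396 against 194.9 CPM. Mir6236, Clec4e, Tnfsf9, Traf1, Plac8 and Oasl1 followed. On the lower side, after Lyz2, were Mmp12, a macrophage elastase gene, at 86.0 against 161.8 CPM, Spp1, the gene for osteopontin, at 420.1 against 647 CPM, and Acp5, at 121 against 192 CPM. Ftl1-ps1, Gclm, Ccl7, Atp6v0d2, Itgax and Oser1 followed. Repair-associated macrophage genes were lower, 12 of 15, with a median of −0.20 (−0.24 to −0.15). Efferocytosis genes, 18 of 22, and PPAR and LXR targets, 12 of 13, were lower with medians of −0.11 and −0.13. Monocyte genes had a median of 0.17, stress and immediate early genes 0.14, inflammatory genes 0.098 and interferon-response genes 0.087. The inflammatory median was −0.044 in male and 0.36 in female cells and −0.014 in cluster 3 alone, and the interferon-response median was 0.12 in male and 0.46 in female cells. Medians of repair-associated and monocyte genes were not taken in single clusters, so they were not separated from a different mix of clusters. Female cells made up 36.0% of sexed monocyte/macrophage-like cells in the Gsdmd cKO library and 56.1% in the floxed control. All 10 fast-fibre transcripts, which macrophages are not known to make, were higher with a median of 0.99.

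In MuSC/myoblast-like cells at 10 days, cell cycle genes were lower in the Gsdmd cKO library, 11 of 12, with a median of −0.83 (−0.95 to −0.71), and all 9 cholesterol synthesis genes were higher, with a median of 0.78 (0.70–0.99). Ube2c, which acts in mitotic exit, was at 21.1 against 99.8 CPM and Cenpf, a kinetochore gene, at 50.3 against 160.1 CPM, with Cenpa and Prc1 next. Msmo1 was at 66.6 against 22.0 CPM, Idi1 at 70.6 against 24.8 CPM and Cyp51 at 95.7 against 36.4 CPM, all enzymes of the cholesterol pathway, and Cxcl10 was at 348 against 147 CPM. Fast-fibre transcripts had a median of 0.55 in these cells. Cluster 28, whose leading genes include Myod1 and Rrm2, held 1.86% of the MuSC/myoblast-like cells in the Gsdmd cKO library and 5.61% in the floxed control. The cell cycle median was −0.48 in male and −0.48 in female cells alone. In cluster 13 alone the 4 measured cell cycle genes, fewer than the 5 set for a list median, had a median of 0.21, of the opposite sign, and the cholesterol synthesis median was 0.77.

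Endothelial-like cells at 10 days had more inflammatory transcripts in the Gsdmd cKO library, 6 of 6 with a median of 0.73, and more stress and immediate early transcripts, 20 of 20 with a median of 0.87. Cxcl9 was at 316 against 100.7 CPM, Cxcl10 at 261 against 88.3 CPM and Selp, the gene for the leukocyte-binding P-selectin, at 88.5 against 28.8 CPM, with Hspa1a next. Wdfy1, Timp4, AU020206 and Tcp11l2 were furthest lower. In FAP/fibroblast-like cells the inflammatory list was lower, 10 of 10 with a median of −0.27, and stress genes had a median of −0.20. Lrrc15, a marker of matrix-producing fibroblasts, was at 28.1 against 75.1 CPM there, and Rrad, Tm4sf1 and Rcan1 were also lower. Higher in those cells were Mir6236, Lars2, Rn18s-rs5, a ribosomal RNA fragment, and Isg15.

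At 10 days 9 genes were at least 2-fold higher and 2 lower of 3068 measured in monocyte/macrophage-like cells, 6 and 8 of 3428 in MuSC/myoblast-like cells, 0 and 3 in FAP/fibroblast-like cells and 13 and 4 in endothelial-like cells. Those higher in monocyte/macrophage-like cells were Lyz1, Cxcl9, Hspa1b and 6 muscle-fibre transcripts, Myl1, Mylpf, Ckm, Tnnt3, Acta1 and Pgam2, the 6 named after their values were seen. Those lower were Lyz2 and the haemoglobin gene Hbb-bs in monocyte/macrophage-like cells, Lrrc15, Lyz2 and Hbb-bs in FAP/fibroblast-like cells, and Lyz2, Hbb-bs, Hba-a1 and Hba-a2 in endothelial-like cells. In MuSC/myoblast-like cells they were Lyz2, Hbb-bs, the neutrophil marker S100a9, Cenpf, Ube2c, Cenpa, Prc1 and Birc5. Neutrophil transcripts stood there at 13.5 CPM in the Gsdmd cKO library and 124 CPM in the floxed control. The haemoglobin genes, S100a9, Birc5, and Lyz2 outside monocyte/macrophage-like cells, were named after their values were seen. Haemoglobin transcripts, a sign of red cell RNA, stood in monocyte/macrophage-like cells at 5.23 CPM in the Gsdmd cKO library and 139 CPM in the floxed control. The monocyte/macrophage-like share was 9.42% (8.80–10.1) in the Gsdmd cKO library and 11.5% (10.9–12.2) in the floxed control, a difference of −2.11 points (−3.00 to −1.22). MuSC/myoblast-like cells made up 8.54% and 6.24%, a difference of 2.30 points (1.53–3.07), endothelial-like cells 17.9% and 29.1%, and myocyte-like cells 22.2% and 12.4%. These are shares of kept cells, and the mitochondrial limit was exceeded by 17.2% of barcodes in the Gsdmd cKO library and 4.43% in the floxed control. Both libraries held cells of both sexes, with 46.7% (45.3–48.1) female among sexed cells of the Gsdmd cKO library and 60.0% (58.8–61.1) in the floxed control. Of the 11 genes that were 2-fold apart in monocyte/macrophage-like cells, 4 were over 2-fold apart in male and in female cells taken alone, and across 2983 genes the ratios in male and female cells had a Pearson correlation of 0.29. Cxcl9 was at 256 against 44.7 CPM in male cells and 28.1 against 27.5 CPM in female cells.

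In uninjured muscle, monocyte/macrophage-like cells of the Gsdmd cKO library had fewer monocyte transcripts, with 9 of 12 genes lower and a median log2 ratio of −1.02 (−1.19 to −0.73), and more resident macrophage transcripts, with 16 of 19 higher and a median of 0.39 (0.19–0.54). Chil3, a gene of monocytes and alternatively activated macrophages, was at 16.8 CPM (9.60–27.3) against 456 CPM (396–523), Plac8 at 200.5 against 1027 CPM and the chemokine receptor gene Cx3cr1 at 90.3 against 602 CPM. Inflammatory genes, 12 of 14, and interferon-response genes, 12 of 13, were lower, with medians of −0.94 and −0.44, and Il1b was at 297 against 1415 CPM. The pyroptosis list was lower too, 8 of 10, with a median of −0.55, and complement genes had a median of 0.64. Itgal, Mucl1, Clec4e, Ceacam1 and Gvin3 were also among the genes furthest lower. Cluster 4, with Plac8 and Chil3, and cluster 34, with Itgal, held 2.72% each of these cells in the Gsdmd cKO library, 5 cells each, and 9.64% and 12.0% in the floxed control, 8 and 10 cells. In cluster 3 alone the medians were −0.31 for 5 measured monocyte genes, 0.064 for resident macrophage, −0.97 for inflammatory, −0.30 for interferon-response and −0.49 for pyroptosis genes. With cells thinned to 1000 UMIs the monocyte median was −0.36 over 7 measured genes. The genes with the largest ratios on the higher side were Fkbp5, a glucocorticoid-inducible co-chaperone gene, at 186 CPM (159–215) against 8.82 CPM (2.40–22.6), Tsc22d3, which encodes glucocorticoid-induced leucine zipper, at 1179 against 227 CPM, Got1, Tmem37, Klf9, Rn18s-rs5, Jdp2, Lyz1, Fam118a and the clock gene Per1.

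Other classes of the uninjured libraries differed as well. Cholesterol synthesis genes were lower in MuSC/myoblast-like cells of the Gsdmd cKO library, 7 of 8 with a median of −1.45 (−1.62 to −1.24), and in FAP/fibroblast-like cells, 8 of 8 with a median of −1.33. Idi1 was at 13.5 against 86.2 CPM in MuSC/myoblast-like cells, with Cyp51 and Nrbp2 also lower, and Rn18s-rs5, Ddit4, Fkbp5 and Plekhf1 higher. Quiescence genes had a median of −0.35, or −0.17 under TMM scaling, and extracellular matrix genes 0.66 in these cells. Oxidative phosphorylation genes were higher in FAP/fibroblast-like, MuSC/myoblast-like and endothelial-like cells, with medians of 0.31, 0.37 and 0.51, the second of which was 0.57 under TMM scaling, and glycolysis genes had a median of 0.61 in endothelial-like cells. FAP/fibroblast-like cells had more Ddit4, at 100.7 against 10.6 CPM, Angptl4, Tsc22d3 and Sgk1, and less Postn, the gene for the matrix protein periostin, at 76.4 against 589.9 CPM, Mrgprg, Smpd3 and Daglb. Endothelial-like cells had more Depp1, at 401 against 54.2 CPM, Rbp7, Fkbp5 and Dusp8, and less H1f2, Zfp36l1, Nuak1 and Lratd2.

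Fast-fibre transcripts were higher in the uninjured Gsdmd cKO library in every class above, with medians of 2.00 in monocyte/macrophage-like, 2.07 in FAP/fibroblast-like, 1.84 in MuSC/myoblast-like and 1.97 in endothelial-like cells. The monocyte/macrophage-like comparison rested on 184 and 83 cells, with 68 genes at least 2-fold higher and 160 lower of 3332 measured. TMM scaling shifted the median by 0.12 and gave 90 higher and 113 lower, and thinning to 1000 UMIs per cell gave 116 higher and 42 lower. In MuSC/myoblast-like cells 44 genes were higher and 42 lower of 2883, or 59 and 13 under TMM scaling, which shifted the median by 0.21, 49 and 83 with a pseudocount of 1 CPM, and 46 and 62 under the stricter cell filter. The counts were 41 and 37 in FAP/fibroblast-like cells, or 48 and 29 under TMM scaling with a shift of 0.15, and 77 and 81 in endothelial-like cells, or 97 and 62 with a shift of 0.11. The monocyte/macrophage-like share was 3.42% (2.95–3.94) in the Gsdmd cKO library and 2.58% (2.06–3.19) in the floxed control, a difference of 0.843 points (0.0746–1.58). The MuSC/myoblast-like share was 12.0% against 7.83%, a difference of 4.22 points (2.92–5.50), or 1.32 points (−0.837 to 3.43) under the stricter cell filter, and the FAP/fibroblast-like share 23.4% against 8.01%.

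The comparison of EET with control treatment asks how EET alters the cells of cardiotoxin-injured wild-type muscle. At 3 days the largest ratio in monocyte/macrophage-like cells was that of Hmox1, the gene for heme oxygenase, at 888 CPM (881–896) in the EET library and 405 CPM (400.1–409.9) in the control treatment library. Haemoglobin transcripts stood in these cells at 8.36 CPM in the EET library and 2.45 CPM in the control treatment library. They were also higher with EET in the other classes compared at 3 days. Whether this difference in red cell RNA bears on Hmox1 was not tested. Gclm, a glutathione synthesis gene, was at 117 against 65.0 CPM and Txnrd1, which encodes thioredoxin reductase, at 138 against 97.0 CPM. Gbp2, Isg15, Zbp1 and Oas3, all interferon-inducible, were among the 10 highest, with Rsrp1, Tmem140 and Tsc22d3. Interferon-response genes were higher, 18 of 21, with a median of 0.21 (0.20–0.24), and all 8 MHC class II genes with a median of 0.17. The interferon-response median was 0.36 and 0.38 in clusters 2 and 6 alone and −0.0017 in cluster 8 alone. Inflammatory genes were lower, 12 of 14, with a median of −0.44 (−0.46 to −0.42), led by Cxcl2 at 369 against 749.9 CPM and Tnfaip3 at 40.9 against 75.2 CPM. Stress and immediate early genes were lower, 14 of 16, with a median of −0.35. Furthest lower were Ifrd1, at 126 against 219 CPM, H2ac24, Rasgef1b, Fosb, Cd14, Klf4, Cd83, Nr4a2, Malt1 and Ier3. The median of the pyroptosis list was 0.085 and that of the arachidonate and epoxyeicosanoid enzymes 0.022, the latter within those of random lists and with a mean of −0.022.

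Inflammatory genes were also lower at 3 days in FAP/fibroblast-like cells of the EET library, 10 of 10 with a median of −0.81, and stress genes 18 of 18 with a median of −0.49. Cxcl10 was at 63.0 against 231 CPM, Il6, the gene for interleukin-6, at 23.8 against 65.9 CPM, Cxcl5 at 56.1 against 125 CPM, and Myoc was also lower, while Mest, Nrep, Creb3l1 and Elavl1 were higher. Endothelial-like cells had 16.2 against 82.8 CPM of the adhesion gene Vcam1, 35.9 against 147 CPM of Cxcl10, 47.6 against 149 CPM of Cxcl9 and 44.9 against 112 CPM of Icam1, and angiogenesis and endothelial activation genes were lower, 11 of 14, with a median of −0.18. Atxn7, Thbs1, Racgap1 and Plin2 were higher there. These cells numbered 134 and 140, and they also had more transcripts of macrophage genes, with medians of 0.92 for MHC class II and 0.39 for efferocytosis genes. Neutrophil-like cells, 283 and 241 in number, had more interferon-response transcripts, 21 of 21 with a median of 1.57. Ifit3b was at 414 against 35.3 CPM, Ifit1 at 576 against 97.0 CPM, and Lrg1 and Ifi47 were also higher. Il23a was at 81.0 against 341 CPM, with Cxcl3, of which 1 count was seen in the EET library, Strbp and Adrm1 also lower. Haemoglobin transcripts in these cells stood at 2231 CPM in the EET library and 2.94 CPM in the control treatment library. MuSC/myoblast-like cells had more Ogt, Krt8, Hk1 and Ccdc107 and less Plk2, at 67.2 against 113 CPM, H2ac24, Mir6236 and Sgk1. Their medians were 0.62 for MHC class II, 0.16 for extracellular matrix, −0.073 for myogenic commitment and −0.23 for stress genes. The macrophage transcripts Cd74, at 198 against 119 CPM, Apoe, at 1247 against 986 CPM, and Pf4, at 58.5 against 46.1 CPM, were higher in these cells as well, and the MHC class II value was not separated from free RNA of macrophages. These 3 were named after their values were seen.

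At 3 days 1 gene, Hmox1, was at least 2-fold higher and 1, Cxcl2, lower of 3094 in monocyte/macrophage-like cells, or 1 and 0 under TMM scaling, and 2 were higher and 1 lower of 3299 in MuSC/myoblast-like cells. Those in MuSC/myoblast-like cells were the collagen gene Col1a1 and the fast-fibre gene Tnnc2, both higher, and the stress gene Atf3, which was lower. The FAP/fibroblast-like cells had 1 gene higher, Fabp4, named after its values were seen, and 6 lower. There were 17 and 7 in endothelial-like cells and 83 and 49 in neutrophil-like cells. The monocyte/macrophage-like share was 72.6% (71.7–73.4) with EET and 71.2% (70.3–72.1) with control treatment, a difference of 1.35 points (0.148–2.56). The MuSC/myoblast-like shares were 1.42% and 1.62%, a difference of −0.197 points (−0.534 to 0.135).

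At 10 days interferon-response genes were higher in monocyte/macrophage-like cells of the EET library, 18 of 19, with a median of 1.05 (0.94–1.07). Irf7, the gene for a transcription factor of the interferon response, was at 235 CPM (229.5–241) against 56.8 CPM (53.6–60.1), Rtp4 at 147 against 36.1 CPM, Oasl2 at 173 against 53.9 CPM and Ifit3 at 109 against 37.8 CPM. Oas3, Lgals3bp, Ifit2, Ifi27l2a, Ifitm3 and the chemokine gene Ccl12, at 216 against 94.1 CPM, were the other genes furthest higher. Inflammatory genes were higher, 18 of 19, with a median of 0.48, as were resident macrophage genes, 10 of 12, with a median of 0.37, MHC class II genes, 0.31, stress genes, 0.37, senescence genes, 0.31, complement genes, 0.28, and growth factors, 0.27. The floxed control, without EET, lay above the same control treatment library by medians of 1.25 for inflammatory, 1.07 for stress and 0.96 for MHC class II genes. For these lists the difference with EET was thus not separated from a difference between libraries unrelated to EET. Cluster 3 held 2031 of the 2785 cells of this class with EET and 1716 of 2709 with control treatment. The resident macrophage median was not taken in that cluster alone. The median of the arachidonate and epoxyeicosanoid enzymes, 0.14 over 11 genes, lay within those of random lists. Fast-fibre transcripts had a median of 0.58. Furthest lower were Mir6236, at 376 against 1033 CPM, Lilrb4a, Paxbp1, the histone genes H1f5 and H1f4, the integrin gene Itgb1, at 291 against 580.1 CPM, Macf1, the nuclear RNA Malat1, at 10322 against 19399 CPM, Galc and Ddx23.

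Interferon-response genes were also higher with EET at 10 days in FAP/fibroblast-like cells, 10 of 12 with a median of 0.81, and in endothelial-like cells, 17 of 17 with a median of 0.73. MHC class II genes in FAP/fibroblast-like cells had a median of 0.99, which was not separated from free RNA of macrophages. Dlk1, a gene of growth and regeneration, was at 833 against 333 CPM there, with Nr4a1, Zfp36 and Lgals3bp also higher, and the chemokine gene Cxcl14 was at 179 against 499.6 CPM, with Mir6236, H1f4 and Prg4, which encodes lubricin, also lower. Endothelial-like cells had 228 against 62.5 CPM of Irf7, with Ifit1, Rtp4 and Igfbp3 next, and less H1f4, Mir6236, Kcnq1ot1 and Syne1.

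MuSC/myoblast-like cells of the EET library at 10 days had more cell cycle transcripts, 15 of 15 genes with a median of 1.11 (0.99–1.27), and more transcripts of myogenic commitment and fusion, 11 of 13 with a median of 0.69 (0.45–0.81). The floxed control, without EET, lay above the same control treatment library by a cell cycle median of 1.16, or 0.74 in its male cells. The cell cycle difference was thus not separated from a difference between libraries unrelated to EET. Myog, the gene for the differentiation factor myogenin, was at 242 CPM (219–267) against 34.4 CPM (24.9–46.4), Mymx, which encodes a myoblast fusion protein, at 88.3 against 12.8 CPM, and Cdk1, the mitotic kinase gene, at 60.7 against 7.21 CPM. H2ac24 was also higher. Oxidative phosphorylation genes were higher, 29 of 30, with a median of 0.49, and glycolysis genes had a median of 0.51. Quiescence genes were lower, 10 of 13, with a median of −0.34, among them the stem cell factor gene Pax7, at 357 against 635 CPM. Extracellular matrix genes, 18 of 26, and stress genes were lower with medians of −0.22 and −0.40. Fast-fibre transcripts, of which Acta1, Ckm and Mylpf also belong to the myogenic list, had a median of 0.69 in these cells. Mir6236, Cep128, Medag and Paxbp1 were furthest lower. Cluster 28, with Gal, Myod1 and Rrm2 among its leading genes, held 14.1% of these cells with EET and 4.06% with control treatment, and the class numbered 156 and 197 cells. In cluster 13 alone the medians were 0.34 for myogenic commitment and 0.30 for oxidative phosphorylation genes, and 0.53 over 4 measured cell cycle genes, fewer than the 5 set for a list median. With cells thinned to 1000 UMIs the quiescence median was −0.14 and the stress median −0.24, and under TMM scaling the extracellular matrix median was −0.14.

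At 10 days 18 genes were at least 2-fold higher and 11 lower of 3252 in monocyte/macrophage-like cells, or 26 and 6 under TMM scaling, which shifted the median by 0.12. The MuSC/myoblast-like counts were 51 higher and 31 lower of 3749 genes, or 70 and 18 under TMM scaling, and thinning to 1000 UMIs per cell gave 38 higher and 96 lower. The counts were 14 and 10 in FAP/fibroblast-like cells and 13 and 7 in endothelial-like cells. The monocyte/macrophage-like share was 31.1% (30.2–32.1) with EET and 27.1% (26.2–28.0) with control treatment, a difference of 4.03 points (2.73–5.34), or 2.19 points (0.698–3.69) under the stricter cell filter. Unnamed cells were 15.2% with EET and 21.6% with control treatment. With unnamed cluster 10 counted in the class the difference was 0.572 points (−0.782 to 1.93), and with clusters 10 and 31 it was −1.03 points (−2.40 to 0.344), so the direction rests on cells that the naming rule left out. MuSC/myoblast-like cells made up 1.74% and 1.97%, a difference of −0.227 points (−0.619 to 0.167). FAP/fibroblast-like cells made up 15.9% and 8.63%, and tenocyte-like cells 4.55% and 8.08%.

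**Figure D4:**
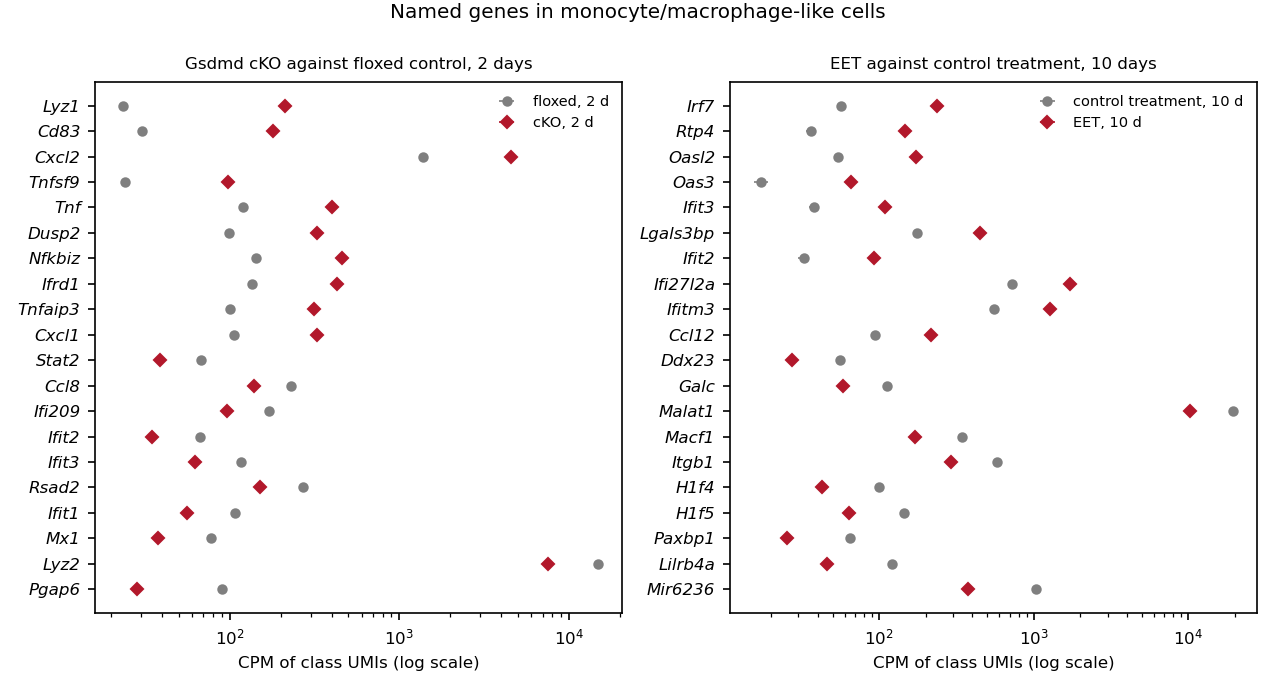
Points give CPM on a log axis, with exact 95% Poisson intervals, of the 20 named genes in monocyte/macrophage-like cells for Gsdmd cKO and floxed control at 2 days and for EET and control treatment at 10 days. Irf7 lies at 235 CPM with EET and 56.8 CPM with control treatment.

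The pair of control libraries at 10 days, floxed control against control treatment, shows how far libraries of different experiments lie apart. In monocyte/macrophage-like cells 98 genes were at least 2-fold higher and 22 lower of 3303, with an inflammatory median of 1.25, 19 of 20 genes higher, and a stress median of 1.07. MHC class II genes had a median of 0.96, interferon-response genes 0.45, cell cycle genes −1.02 and fast-fibre transcripts 1.32. Tnf was at 246 against 48.7 CPM, Cd83 at 1133 against 258 CPM, Hspa1a at 194.9 against 27.3 CPM and Spp1 at 647 against 2208 CPM. Rn18s-rs5 was at 5576 against 46797 CPM. The inflammatory median was 1.31 in FAP/fibroblast-like and 1.05 in MuSC/myoblast-like cells. MuSC/myoblast-like cells had 59 genes higher and 47 lower, or 73 and 36 under TMM scaling, and their cell cycle median was 1.16. The counts were 69 and 24 in FAP/fibroblast-like and 35 and 12 in endothelial-like cells. These libraries also differ in genotype, in treatment and in the Cell Ranger version of their headers. The pair may thus overstate the spread between libraries of the same experiment. It also differs in sex, with 60.0% female among sexed cells of the floxed control and 0.0192% in the control treatment library. With male cells of the floxed control alone, monocyte/macrophage-like cells had 114 genes higher and 20 lower, and medians of 1.49 for inflammatory, 0.87 for stress, 0.61 for interferon-response and −0.92 for cell cycle genes.

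The libraries over time within each genotype ask how macrophages of injured muscle differ from those of resting muscle. At 2 days, monocyte/macrophage-like cells of the floxed control had more repair-associated transcripts than in uninjured muscle, with a median of 1.91, and fewer resident macrophage transcripts, with a median of −2.12. Spp1 was at 10527 against 17.6 CPM, Fabp5, a lipid-binding protein gene, at 5820 against 174 CPM and Ctsd, a lysosomal protease gene, at 5192 against 304 CPM. Gpnmb was at 1256 CPM at 2 days, and 1 count of it was seen in uninjured muscle. Retnla, a gene of alternatively activated macrophages, was at 1.33 against 8637 CPM, Mgl2 at 4.67 against 928 CPM, Cd163 at 12.2 against 388 CPM and Lyve1, a marker of resident macrophages, at 10.6 against 349.6 CPM. Glycolysis genes had a median of 1.61, oxidative phosphorylation genes 0.91 and MHC class II genes −3.07. In the Gsdmd cKO libraries the medians at 2 days were 2.51 for repair-associated, −2.73 for resident macrophage and 1.44 for glycolysis genes, and Spp1 was at 8942 against 2.10 CPM. Inflammatory genes had a median of 1.67 in the Gsdmd cKO libraries and −0.10 in the floxed control, the latter within those of random lists. In uninjured muscle this list had a median of −0.94 between Gsdmd cKO and floxed control, from 184 and 83 cells. The gap between the genotypes over time thus also holds this difference at the start. The pairs over time differ in their clusters. Cluster 3, with Ccl8, Mrc1 and C1qa, held 73.5% of these cells in the uninjured floxed control and 89.7% in the uninjured Gsdmd cKO library. At 2 days clusters 0, with Arg1, Ccl7 and Spp1, and 4, with Plac8, Chil3 and Ly6c2, held 57.4% and 36.6% in the floxed control and 58.0% and 38.5% in the Gsdmd cKO library.

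At 10 days cluster 3 again held 79.3% of monocyte/macrophage-like cells in the floxed control and 78.3% in the Gsdmd cKO library. Repair-associated genes had medians of 2.35 and 2.28 against uninjured muscle in the floxed control and the Gsdmd cKO, efferocytosis genes 1.17 and 0.69, and monocyte genes −1.41 and 0.47. Between Gsdmd cKO and floxed control, monocyte genes had medians of −1.02 in uninjured muscle and 0.17 at 10 days. The gap in monocyte genes between the genotypes over time thus also holds the difference of the uninjured pair. Gdf15, a stress-response cytokine gene, was at 560.2 against 17.6 CPM in the floxed control and 748 against 27.3 CPM in the Gsdmd cKO. Retnla was lower, at 96.2 against 8637 CPM and 142 against 6485 CPM. In monocyte/macrophage-like cells 514 genes were at least 2-fold higher and 461 lower at 2 days in the floxed control, or 892 and 333 under TMM scaling with a shift of 0.27. The Gsdmd cKO libraries had 506 and 370, or 807 and 293 with a shift of 0.22. At 10 days the counts were 214 and 169 in the floxed control, or 295 and 133 with a shift of 0.16, and 270.0 and 135 in the Gsdmd cKO. All uninjured cells with sex-linked transcripts were female and nearly all of those at 2 days male, so time and sex cannot be told apart at 2 days. Female cells of the 10-day libraries alone, 506 in the floxed control and 185 in the Gsdmd cKO, gave medians against uninjured muscle of 2.197 and 1.61 for repair-associated, 1.23 and 0.70 for efferocytosis and −1.87 and −0.16 for monocyte genes. Their counts were 234 higher and 192 lower in the floxed control and 280 and 125 in the Gsdmd cKO.

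Muscle stem cells and fibroblasts also differed with time. At 2 days all 27 cell cycle genes were higher in MuSC/myoblast-like cells of both genotypes, with medians of 3.805 in the floxed control and 3.35 in the Gsdmd cKO, and quiescence genes had medians of −2.66 and −2.91. Gal, the gene for the neuropeptide galanin, was at 963 against 7.07 CPM in the floxed control and 1150.0 against 26.4 CPM in the Gsdmd cKO, and Chodl was at 0.333 against 1447 CPM and 1.12 against 1054 CPM. Cluster 28 held 100% of these cells at 2 days, and cluster 13, with Pax7 and Chodl, held 100% and 99.9% in uninjured muscle. In FAP/fibroblast-like cells at 2 days Cxcl5, a neutrophil-attracting chemokine gene, was at 700.0 against 4.55 CPM in the floxed control, and Pi16, a gene of adventitial progenitors, at 17.2 against 1498 CPM. At 10 days extracellular matrix genes had medians of 0.73 and 0.76 in FAP/fibroblast-like cells of the floxed control and the Gsdmd cKO, and Dlk1 was at 1224 against 9.87 CPM and 1276 against 26.3 CPM. Clusters 16, 19 and 5 held 98.1%, 97.7% and 90.5% of the FAP/fibroblast-like cells of the floxed control in uninjured muscle, at 2 days and at 10 days.

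Ratios were also correlated between comparisons, across genes, which are not independent replicates. In monocyte/macrophage-like cells, those of Gsdmd cKO at 2 days had a Pearson correlation of −0.56 with those of EET at 3 days over 2693 genes and of 0.25 with those of Gsdmd cKO at 10 days over 2607 genes. Only Lyz1 was at least 2-fold higher at both times, against 0.0142 genes expected from the product of the counts over the genes measured. Of the genes measured at both times, Lyz1 was also the only one at least 2-fold higher at 10 days. No other gene could therefore have overlapped, and this overlap says nothing of genes beyond Lyz1. In endothelial-like cells the correlation between the Gsdmd cKO comparisons at 2 and 10 days was 0.39 over 3218 genes. It was 0.093 over 2364 genes in MuSC/myoblast-like cells and −0.22 over 2509 genes in FAP/fibroblast-like cells. In endothelial-like cells 6 genes were at least 2-fold higher at both times, against 0.0684 expected, and they were Atf3, Igfbp5, Vcam1, Cxcl9, Cxcl10 and Fos. Atf3, Igfbp5 and Vcam1 were named after their values were seen. Igfbp5 at 10 days was higher in female cells alone, at 389 against 28.5 CPM, and lower in male cells, at 32.4 against 65.7 CPM, while the sexed cells at 2 days were male. In FAP/fibroblast-like cells 4 genes were at least 2-fold higher in Gsdmd cKO at 2 days and lower with EET at 3 days, against 0.0329 expected. They were Cxcl10, Il6, Cxcl2 and Atf3, the last named after its values were seen. These genes belong to the inflammatory and stress lists, whose medians in this class were higher with Gsdmd cKO and lower with EET. The expected counts treat genes as varying independently, which members of such lists did not. An overlap above the expected count is therefore no evidence of a link between comparisons.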

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

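The tests in this part of cell mixing, of depth and of a linked chromosome segment were chosen before their values were known, and those of activation between libraries, of confinement to Cre-active classes, of interferon between libraries, of a replaced Lyz2 copy and of reads shared between paralogs were chosen after seeing the results.

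Some results differed in sign between times of the same contrast, and these differences between times were not tested, since each rests on 1 library per group. The monocyte/macrophage-like share was higher in the Gsdmd cKO than in the floxed control library by 0.843 points in uninjured muscle and by 3.96 points at 2 days, and differed by −2.11 points at 10 days. In these cells the median log2 ratio of monocyte genes between Gsdmd cKO and floxed control was −0.24 at 2 days and 0.17 at 10 days, and that of interferon-response genes was −0.52 and 0.087. Between EET and control treatment, inflammatory genes in monocyte/macrophage-like cells had medians of −0.44 at 3 days and 0.48 at 10 days, senescence genes −0.065 and 0.31, and stress and immediate early genes −0.35 and 0.37. In MuSC/myoblast-like cells the same contrast gave 0.16 and −0.22 for extracellular matrix genes and −0.073 and 0.69 for myogenic commitment genes.

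Inflammatory genes were higher in the Gsdmd cKO library at 2 days, by a median of 1.17 in monocyte/macrophage-like cells. A mix of clusters could give this, but within clusters 0 and 4 alone the lower median was 1.19, which argues against it. An effect confined to classes with Lyz2-Cre activity might give it, with free RNA of macrophages and neutrophils in the other classes, but with that RNA taken off the median in FAP/fibroblast-like cells was 0.99 (0.33–1.20 over list members), above the 0.29 set as the limit for confinement, and 1.03 (0.11–1.28) over 8 genes with mostly their own RNA, which argues against it there, while 1.11 (0.61–1.45) in endothelial-like cells, or 0.92 (−0.62 to 2.12) over 5 such genes, and 0.61 (−0.45 to 1.27) in MuSC/myoblast-like cells left it open. Activation that differs between any pair of libraries, as handling gives, predicts a correlation with the ratios between the control libraries in each class, and it was 0.42 across 2729 genes of monocyte/macrophage-like cells, or 0.33 without the inflammatory and stress lists, and 0.36 in FAP/fibroblast-like, 0.13 in MuSC/myoblast-like and 0.067 in endothelial-like cells, which left it open. A signal from Gsdmd-deficient cells to other classes could give the same pattern and was not separated from handling. That would need further libraries per group, each handled separately.

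Interferon-response genes were higher in the EET library at 10 days, by a median of 1.05 in monocyte/macrophage-like cells. The share of the interferon cluster might give this, but in cluster 3 alone the median was 1.27, which argues against it. Fewer UMIs per cell in the control treatment library could also give it. With cells of at least 1000 UMIs thinned to that number, and the rest left out, the median was 0.90, which argues against it for such cells. A difference between libraries unrelated to EET remained open, since the largest absolute median between libraries without EET at 10 days was 0.71, for Gsdmd cKO against control treatment, with 0.45 between the control libraries and 0.087 between Gsdmd cKO and floxed control.

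Lyz2 was lower and Lyz1 higher in the Gsdmd cKO libraries at all 3 times. Cre in place of 1 Lyz2 copy could lower Lyz2 to a log2 ratio near −1, but its ratios, between −1.18 and −0.98, are the pattern itself and had been seen, so they do not decide this. Reads shared between the paralogs might put a fixed share of Lyz2 tags under Lyz1, but the excess of Lyz1 over the floxed control was 12.6% of Lyz2 in uninjured muscle, 2.49% at 2 days and 9.58% at 10 days, which argues against such a fixed share as the whole cause. A linked chromosome segment from another strain could alter Lyz1. Of 10 measured neighbours of Lyz2, 0% differed at both 2 and 10 days, with an upper limit of 30.8%, against 0.269% of all genes. By the rule first written, a share this low would have argued against a segment. The rule used here instead asked for a low upper limit, which even 0% of 10 genes did not meet, so the segment was left open.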

How the results depend on the processing

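With 1 library per group, no alternative can separate treatment or genotype from the library, and the uninjured pair is further limited by 83 monocyte/macrophage-like cells in the floxed control. Of the 2-fold counts under alternatives, 120 stayed within 1.5 times the reported count and 28 did not. Of the share differences 54 stayed within their interval, 5 moved and 1 was reversed, of the Gsdmd ratios 22 stayed and 2 moved, and of the list medians 314 stayed and 76 moved. List medians were recomputed with a pseudocount of 1 CPM and TMM scaling, which moved 23 and 53 of 195 beyond their counting interval, and 20 under TMM scaling lay over 1.5 times apart. No Gsdmd ratio changed sign under an alternative run for it, and no list median did under this pair.

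Of the alternatives chosen after seeing the data, counting unnamed cells as monocyte/macrophage-like altered 2 share differences. With cluster 10 they were 0.696 points for Gsdmd cKO at 2 days and 0.572 points for EET at 10 days, and with clusters 10 and 31 they were 0.660 and −1.03 points, the last reversed.

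The larger direction of some 2-fold counts changed. In monocyte/macrophage-like cells, thinning gave 116 higher and 42 lower for Gsdmd cKO in uninjured muscle, and a minimum of 20 CPM gave 690 and 703 for the floxed control at 2 days against uninjured. In MuSC/myoblast-like cells, thinning gave 11 and 13 for Gsdmd cKO at 2 days and 38 and 96 for EET at 10 days, and in uninjured muscle a pseudocount of 1 CPM gave 49 and 83 and the stricter filter 46 and 62. For Gsdmd cKO at 10 days in the same class, a minimum of 100 CPM gave 3 and 2, per-cell CPM 5 and 2, kept doublets 6 and 5 and male cells alone 13 and 8. In uninjured endothelial-like cells TMM scaling gave 97 and 62. Some list medians were also taken in female or male cells, in single clusters or thinned, chosen after seeing the data. Of those reported, the ones that then changed sign were stress genes in MuSC/myoblast-like cells for Gsdmd cKO at 2 days, −0.0053 when thinned, inflammatory genes in monocyte/macrophage-like cells for Gsdmd cKO at 10 days, −0.014 in cluster 3 and −0.044 in male cells, interferon-response genes in these cells for EET at 3 days, −0.0017 in cluster 8, cell cycle genes in MuSC/myoblast-like cells for Gsdmd cKO at 10 days, 0.21 over 4 genes in cluster 13, and monocyte genes of the Gsdmd cKO at 10 days against uninjured, −0.16 in female cells. The stricter cell filter left too few cells for some counts, so these have no value under it.

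With a minimum of 100 CPM fewer genes were measured, and counts dropped for that reason. In monocyte/macrophage-like cells they were 128 for Gsdmd cKO in uninjured muscle, 607 and 226 for the floxed control at 2 and 10 days against uninjured, and 556 and 238 for Gsdmd cKO. In MuSC/myoblast-like cells they were 46, 7 and 5 for Gsdmd cKO in uninjured muscle, at 2 and at 10 days, and 0 and 47 for EET at 3 and 10 days. A minimum of 20 CPM measured more genes and gave 4 in monocyte/macrophage-like and 5 in MuSC/myoblast-like cells for EET at 3 days, 128 in MuSC/myoblast-like cells for EET at 10 days, and 576 for the floxed control at 10 days against uninjured.

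Thinning to 1000 UMIs per cell left fewer counts and gave 148 and 24 in MuSC/myoblast-like cells for Gsdmd cKO in uninjured muscle and at 2 days, 46 and 134 for EET at 3 and 10 days, 664 in monocyte/macrophage-like cells of the floxed control at 10 days against uninjured, and a Gsdmd log2 ratio of −0.84 at 2 days. A pseudocount of 1 CPM gave 132 in MuSC/myoblast-like cells of uninjured muscle and 152 for EET at 10 days, where the smaller addition leaves low counts less damped.

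For the remaining values the cause was not tested. Resolutions of 0.5 and 2 gave 147 and 146 in uninjured monocyte/macrophage-like cells, and a resolution of 0.5 gave 6 and 51 in MuSC/myoblast-like cells for EET at 3 and 10 days. The mean of per-cell CPM gave 7 in MuSC/myoblast-like cells for Gsdmd cKO at 10 days, and TMM scaling gave 1 in monocyte/macrophage-like cells for EET at 3 days. The stricter cell filter gave differences in share of 1.32 points for MuSC/myoblast-like cells in uninjured muscle and 2.19 points for monocyte/macrophage-like cells with EET at 10 days. Of the alternatives chosen after seeing the data, female cells alone gave 29 for Gsdmd cKO at 10 days in monocyte/macrophage-like cells, and the largest shared cluster gave a Gsdmd log2 ratio of −1.10 at 2 days.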

Other observations

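An unnamed cluster (cluster 31) had Acp5, Ctsk, Nfatc1 and Mmp9 among its leading genes, which osteoclasts and related giant cells express. It held 239 cells of the control treatment library at 10 days and 71 of the EET library at 10 days. These genes were named after their values were seen. Myocyte-like cells made up 22.2% of the Gsdmd cKO library at 10 days and 12.4% of the floxed control library.

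Of 3213 genes measured in at least 6 of 13 pairs of Gsdmd cKO and floxed control sums, across classes and times, 7 lay at least 0.5 log2 apart in the same direction in every pair in which they were measured. Lyz2 was lower in 10 pairs, with a median of −1.06. Hspa1a, a heat shock gene, was higher in 9 pairs, with a median of 1.04. The fast-fibre transcripts Myl1, Mylpf, Ckm, Tnnt3 and Acta1 were higher in 8 pairs, all in uninjured muscle or at 10 days. At 2 days they were below the minimum level in each class, and the sum of fast-fibre transcripts was 37.4 against 35.2 CPM in monocyte/macrophage-like and 16.9 against 28.1 CPM in endothelial-like cells.

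Sex-linked transcripts showed only female cells in the uninjured libraries, with 4285 and 2604 cells in the Gsdmd cKO and the floxed control. At 10 days the Gsdmd cKO library held 2290.0 female and 2610.0 male cells and the floxed control 4126 and 2752. A further 251 and 363 cells had transcripts of both kinds. In MuSC/myoblast-like cells the median of cholesterol synthesis genes between Gsdmd cKO and floxed control was 0.92 in male and 0.96 in female cells, and that of inflammatory genes in endothelial-like cells was 0.88 and 0.65.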
